A study of Mus musculus with 28 samples.

How the data were processed

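The data are RNA-seq of 28 libraries of mouse uterine tissue from gestation day 18.5, in 3 layers and 2 genotypes. Per the labels' protocols, implantation sites were dissected into decidua, myometrium and mesometrial triangle, RNA was purified from homogenized tissue, and libraries made with the Nugen Universal Plus mRNA kit were sequenced on an Illumina HiSeq instrument. Per the labels, 1 Il33 KO decidua and 1 B6 mesometrial triangle were excluded by the submitters after failed quality control. Per the submitters' processing notes, STAR 2.7.2b, DESeq2 1.24 and the GRCm38 genome were used. The counting tool, the annotation release, the use of strand and any filter are not given in the sources used here.

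The deposited tables, 1 per layer, hold 55536 genes each. Per the file headers, the authors gave a normalized count (signal) per library, rounded to 1 decimal, a variance-stabilized log2 value per library, the log2 fold change and linear fold change (ratio) of Il33 KO against B6, and raw and adjusted p-values. Per the file headers, the deposited tables also give the GC percent of each gene, an annotation and not a measurement. No symbol was given for 3047 genes, and all of these were named by identifier from GENCODE M21. The deposited fold changes and p-values were used only to count and list the authors' calls.

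Read numbers were recovered from the deposited normalized counts. In each library the values were multiples of 1 step, the reciprocal of a size factor, and dividing by it gave whole numbers for at least 99.97% of the values, with a tolerance of at most 0.0900 read, which chance meets for at most 18.0% of values. Size factors were 0.709 to 1.40. Summed recovered reads gave library totals of 18747050 to 36483928, so 3 reads, the limit used for a gene with none, correspond to at most 0.126 CPM in the Il33 KO libraries with no Il33 read. Ratios of Il33 reads carry exact 95% intervals from pooled reads. Recovery was tested on simulated data, where 100% of reads were returned.

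Before the data were examined, edgeR on deposited counts was chosen for each layer, with limma-trend on log2(value + 1) as the stated choice if the tables held no counts. The tables held normalized counts, so limma-trend (limma 3.58.1 in R 4.3.3, with robust empirical Bayes) was the main test within each layer. Genes entered with a normalized count of at least 10 in as many libraries as the smaller group holds, 4 in decidua, 5 in myometrium and 4 in mesometrial triangle. The threshold was a Benjamini-Hochberg adjusted p under 0.05. Interactions between layer and genotype, and B6 layers against each other, were planned only for raw counts. They were added once the values were seen to be whole reads, on the recovered reads of all libraries and of the B6 libraries, with joint median-of-ratios scaling and limma-trend, on 17994 and 16988 genes. Levels of the B6 layers are CPM of recovered reads.

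The 35 gene lists were fixed beforehand. Each list with at least 3 tested members was tested with camera, two-sided, with a preset inter-gene correlation of 0.01 and adjustment over the lists of the layer. Camera with an estimated correlation and fry were run beside it. In each layer members were also adjusted over their list alone.

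Genes are named by a rule fixed beforehand. The rule takes Il33 first, then up to 12 genes per direction past the threshold with a mean of at least 1 CPM, up to 4 called members per list, the 10 genes of smallest p where fewer than 10 passed, and up to 4 abundant members per described list. For interactions it takes the 10 genes of lowest adjusted p per contrast and the genes named before, and for the B6 layers 8 genes per direction at 10 CPM or more and 3 members per list. Genes with a count of 5 or fewer calls that fell under 1 CPM, further members of described lists, Ptgs2 and mt-Nd3 in decidua, and single members called within lists that were not called were named after their values were seen.

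The main steps were tested on simulated data drawn from the real means and library sizes with 200 changed genes. In limma 4.12% of genes changed 2-fold and 55.7% of those changed 4-fold were recovered in decidua, 50.5% and 94.4% in myometrium, and 46.9% and 83.3% in mesometrial triangle. For the interaction of decidua and myometrium the shares were 9.28% and 56.3%, and for B6 mesometrial triangle against myometrium 66.3% and 95%. The simulated list was called in the 3 layers, with 1 unchanged list called in decidua. Genes were drawn independently of each other, so the simulation does not test false list calls among correlated genes.

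Alternatives were DESeq2 1.42.0 and edgeR 4.0.16 on recovered reads, limma-voom, no filter, the fit of all 28 libraries, the replicate number as a block, the trophoblast genes as a covariate, a log2 fold change of at least 1, library size scaling within layers, and each library left out in turn. TMM scaling, library size scaling for the interactions and the B6 layers, edgeR, pseudocounts of 0.5 and 5, sample quality weights, removal of each library's trend on GC content, a block in myometrium of the libraries above the median of Xist, the list without Il33, and both libraries that stood apart left out were added after the data were seen. The planned size factor scaling is that of the deposited values, so TMM took its place. Within each comparison, 100 splits of the libraries into groups of the same sizes were refitted, and in myometrium the smallest camera p over all lists was taken in each. Libraries were checked for duplicates by comparing their reads, and none of 52 pairs within groups was closer than a chi-square of 21.9 per gene. Gm28438 was aligned to mitochondrial transcripts with blastn 2.17.0. Tables and figures were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9. No library was left out of the main fits.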

Results

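RNA was sequenced from 3 layers of the pregnant mouse uterus at gestation day 18.5, the day before birth: whole decidua, myometrium, and the mesometrial triangle, the tissue where vessels enter the implantation site. The mice were C57BL/6 controls (B6) or mice lacking interleukin 33 (Il33 KO). B6 gave 5 libraries of decidua, 5 of myometrium and 4 of mesometrial triangle. Il33 KO gave 4 of decidua, 5 of myometrium and 5 of mesometrial triangle. The labels give up to 5 mice per genotype and do not say which libraries of different layers came from the same mouse. Each table held 55536 genes. Library totals were 22175623 to 32236025 reads in decidua, 18747050 to 35843122 in myometrium and 23825183 to 36483928 in mesometrial triangle. Levels for the genotype comparisons are the deposited normalized counts, given as mean ± SD. Fold changes are log2 of Il33 KO over B6 with their standard error (SE), and adjusted p values are from limma unless another tool is named. Coordinates are those of the files, on GRCm38. Intervals and detection limits cover counting error only.

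Il33 encodes an alarmin held in the nucleus of stromal and barrier cells. The gene (ENSMUSG00000024810) lies on chromosome 19 from 29925114 to 29960718. In B6 it was read in every library, at 4.86 to 5.79 counts per 1000000 reads (CPM) in mesometrial triangle, 2.27 to 4.63 CPM in myometrium and 0.0746 to 0.180 CPM in decidua. In Il33 KO no library exceeded 0.268 CPM. Pooled over libraries, B6 mesometrial triangle held 620 reads of Il33 and Il33 KO 17, a ratio of 45.9 (95% interval 28.5 to 79.4). In myometrium 465 reads stood against 9, a ratio of 54.3 (28.3 to 119). In decidua 19 reads stood against 8, a ratio of 2.04 (0.853 to 5.39), so a difference in decidua was not detectable at this depth. The Il33 KO libraries with no Il33 read had limits of at most 0.126 CPM, the level of 3 reads. Il33 therefore checks the genotype labels in myometrium and mesometrial triangle and not in decidua. The library labelled Il33 KO myometrium replicate 1 is named decidua in 1 of its label fields, and its values were those of myometrium.

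**Figure D1:**
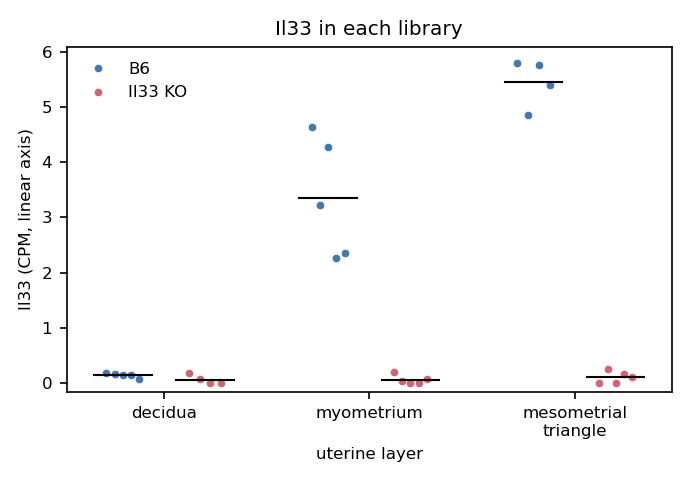
Il33 in each library as CPM of the recovered reads (linear axis) by uterine layer, with 1 point per library and the group mean as a line, B6 in blue and Il33 KO in red. Every B6 library of myometrium and mesometrial triangle lay at 2.27 CPM or more, and no Il33 KO library was above 0.268 CPM.

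The decidua comparison asked what loss of IL-33 changes in the layer next to the placenta just before birth. In Il33 KO decidua 1 gene passed the threshold, a pseudogene, and no placental, labour or immune gene did. Power was low in this layer: on simulated data 4.12% of genes changed 2-fold were recovered. Gm28438 (ENSMUSG00000101939), an unprocessed pseudogene on chromosome 1 from 24612775 to 24613119, rose from 0.18 ± 0.402 to 201.5 ± 40.1 normalized counts. Its transcript is 99.7% identical over 345 bases to mt-Nd3, a mitochondrial gene of respiratory complex I, so reads of the pseudogene and of mitochondrial RNA could be split by the counting and its level is uncertain. Placental hormone genes were abundant in both genotypes, so the dissected decidua held a mixture of maternal and placental transcripts. Prl3b1, which encodes placental lactogen II, had a log2 fold change of -0.13, and Tpbpa, a marker of spongiotrophoblast, -0.39. The labour genes as a list had a mean of -0.14 over 12 tested genes, with Gja1, the gap junction gene of uterine muscle, at -0.73 and Ptgs2, the inducible prostaglandin synthase, at -1.61. Neither passed the threshold.

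Of 15525 genes tested in decidua, Gm28438 (adjusted p = 8.77e-06) held 1 read in the 5 B6 libraries and 819 in the 4 Il33 KO libraries, a ratio of 953 (95% interval 171 to 37693). Genes with an unadjusted p under 0.05 numbered 336 where chance gives 776. edgeR called 1 gene, DESeq2 called 3, and the deposited statistics list 3: Gm28438 and Wdfy1 higher and mt-Nd3, at most 0.602 CPM, lower (adjusted p = 0.0348). Wdfy1, an endosomal adaptor of Toll-like receptor signalling, stood at 984 ± 88.7 normalized counts in B6 and 2328 ± 801 in Il33 KO. Its log2 fold change was 1.18 (SE 0.24, adjusted p = 0.935). It passed in 4 of 15 other settings, among them DESeq2 (adjusted p = 0.0404) and the limma fit of all 28 libraries (adjusted p = 0.00520). With a library left out it passed in 0 of 9 fits. The next genes by p were not past the threshold either (adjusted p = 0.935 each): the receptor phosphatase Ptprf at 0.69, the glycosyltransferase B4galnt4 at 1.15, the endothelial genes Stab1, Gpihbp1, Ushbp1 and Notch4 at 0.99, 1.09, 0.79 and 0.85, the folate receptor Folr1 at 1.65, and the noncoding RNA Lncenc1 at -0.66.

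Vessel, gland, B cell, blood and muscle markers stood together slightly higher in Il33 KO decidua. In the vascular endothelium list 10 of 11 genes were higher (mean 0.38, camera adjusted p = 0.0017, adjusted p = 0.830 with an estimated correlation), among them Pecam1 at 0.44, while the abundant Flt1 stood at 0.01 and Kdr at -0.12. In the uterine epithelium list 12 of 13 were higher (mean 0.57, camera adjusted p = 0.00583, adjusted p = 0.830 with an estimated correlation), with the keratins Krt18 at 0.28 and Krt19 at 0.44. All 7 B and plasma cell genes were higher (mean 0.57, camera adjusted p = 0.0263, adjusted p = 0.830 with an estimated correlation), including the antibody genes Igha at 0.50 and Igkc at 0.61. Erythroid genes were higher in 6 of 7 (mean 0.63, camera adjusted p = 0.0494, adjusted p = 0.844 with an estimated correlation), with globin Hbb-bs at 0.56. Smooth muscle genes were higher in 11 of 12 (mean 0.57, camera adjusted p = 0.0494, adjusted p = 0.844 with an estimated correlation), with Acta2 at 0.80 and Des at 0.04. In each of these 5 lists 0 genes rose in limma over all genes tested and 0 when adjusted over the list alone. Of the 28 other lists tested in decidua, the lowest camera adjusted p was 0.0962.

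The 5 decidual list calls move with single libraries. Il33 KO decidua replicate 4 stood apart, with a first principal component score of 176.5 and a correlation across genes of its deviation with gene GC content of 0.740. It held 22.2 CPM of the nuclear RNA Malat1, against 404 to 1992 CPM in the other decidua libraries, and 7.23 CPM of Xist against 54.8 to 630 CPM. Without it, uterine epithelium had a mean of 0.17 and a test that pointed down (camera adjusted p = 0.891), and erythroid genes a mean of 0.13 (adjusted p = 0.891). B and plasma cells had 0.38 (adjusted p = 0.315) and smooth muscle 0.42 (adjusted p = 0.659), both lost as calls. Vascular endothelium had 0.25 (adjusted p = 0.0163). With sample quality weights the 5 calls were lost: vascular endothelium stood at 0.14 (adjusted p = 0.408), uterine epithelium at 0.29 (0.736), B and plasma cells at 0.31 (0.593), erythroid genes at 0.46 (0.243) and smooth muscle at 0.63 (0.593). Without B6 replicates 2 and 3 in turn, smooth muscle had means of 0.27 and 0.32 (adjusted p = 0.370 and 0.309), and without Il33 KO replicates 2 and 3 its adjusted p was 0.159 and 0.129. Without B6 replicate 4 its mean was 0.88. The smooth muscle call was also lost with the GC trend removed (adjusted p = 0.269), trophoblast genes as a covariate (0.120) or a pseudocount of 5 (0.0564). The adjusted p of B and plasma cells was 0.0601, 0.127, 0.0841 and 0.117 without B6 replicates 2 and 3 and Il33 KO replicates 2 and 3, and their mean was 0.95 without Il33 KO replicate 1. For erythroid genes it was 0.0601, 0.0844, 0.125, 0.520 and 0.0955 without B6 replicates 2, 3 and 4 and Il33 KO replicates 1 and 2. Their mean was 0.40 without Il33 KO replicate 1 and 1.21 without Il33 KO replicate 3. With no filter the erythroid mean was 0.38 and the call was lost (adjusted p = 0.223), as it was with trophoblast genes as a covariate (0.0989). The count of list calls was 2 without B6 replicate 2, B6 replicate 3 or Il33 KO replicate 2.

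The myometrium comparison asked the same of the muscle that contracts at birth. Il33 KO myometrium changed in a small set of genes. Wdfy1 (chromosome 1, 79702262 to 79776143) and the dynein light chain gene Dynlt1b (chromosome 17, 6430112 to 6436293) rose. Il33 itself, the TGF-beta family ligand Gdf3 (chromosome 6, 122605403 to 122610087), the epithelial mucin Muc4 (chromosome 16, 32735886 to 32782391) and the antibody variable segments Ighv14-4 and Ighv1-80 on chromosome 12 fell. Lymphatic endothelial markers were lower as a group by camera with its preset correlation, and not past the threshold with an estimated correlation (adjusted p = 0.185) or fry (0.102). Contractile genes did not pass: the smooth muscle list had a mean of -0.07 (camera adjusted p = 0.609), with actin Acta2 at 0.14 and the myosin heavy chain Myh11 at -0.02, and among labour genes the oxytocin receptor Oxtr stood at -0.19, Gja1 at -0.45 and Ptgs1 at 0.19.

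Of 15545 genes tested in myometrium, 9 passed limma, 3 higher and 6 lower, and 1028 had an unadjusted p under 0.05 where chance gives 777. edgeR called 9, DESeq2 29, and the deposited statistics list 29. Wdfy1 (ENSMUSG00000073643) went from 449.8 ± 49.2 to 1596 ± 366 normalized counts, a log2 fold change of 1.80 (SE 0.16, adjusted p = 0.000126). Dynlt1b (ENSMUSG00000096255) went from 329.6 ± 14.7 to 739 ± 127, a change of 1.15 (SE 0.14, adjusted p = 0.00174); near-identical copies of Dynlt1b lie in the genome, so its level is uncertain. Il33 fell by 5.40 (SE 0.50, adjusted p = 0.000126), and Gdf3 (ENSMUSG00000030117) fell by 2.99, from 70.3 ± 19.6 to 8.58 ± 4.31 (adjusted p = 0.00193). Muc4 (ENSMUSG00000079620) fell by 1.02, from 1777 ± 272 to 879 ± 168 (adjusted p = 0.0125). Ighv14-4 fell by 2.32 and Ighv1-80 by 1.41 (adjusted p = 0.0125 each); variable segments share sequence, so their split is uncertain. The remaining calls were under 1 CPM: Gm28438 (adjusted p = 0.000126) had 0 reads in the 5 B6 libraries and 119 in Il33 KO, at least 30.2-fold higher by the exact 95% interval and 37.8-fold over a floor of 3 reads in the B6 group, and the interferon-inducible Ifi208 fell by 3.71 (adjusted p = 0.0125). Ighv10-3 at -2.30 (adjusted p = 0.0627) and Lhfpl2 and Arid5b at -0.62 each (adjusted p = 0.114) were not past the threshold in the main limma fit. Of 16 other settings Ighv10-3 passed in 5, Lhfpl2 in 3 and Arid5b in 2, DESeq2 among them for each. Ighv10-3 also passed in 3 of 10 fits with a library left out.

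Leaving out single B6 myometrium libraries ended some calls in limma. Ighv14-4 had an adjusted p of 0.0554 without replicate 3. Ighv1-80 had 0.0602, 0.0554 and 0.0524 without replicates 1, 3 and 5. Ifi208 had 0.0587, 0.0514 and 0.0554 without replicates 1, 2 and 3. In a limma fit of all 28 libraries Ighv1-80 (adjusted p = 0.891) and Muc4 (adjusted p = 0.386) were not past the threshold, and with the replicate number as a block they had 0.0722 and 0.0659. The count rose to 17 without Il33 KO replicate 2.

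**Figure D2:**
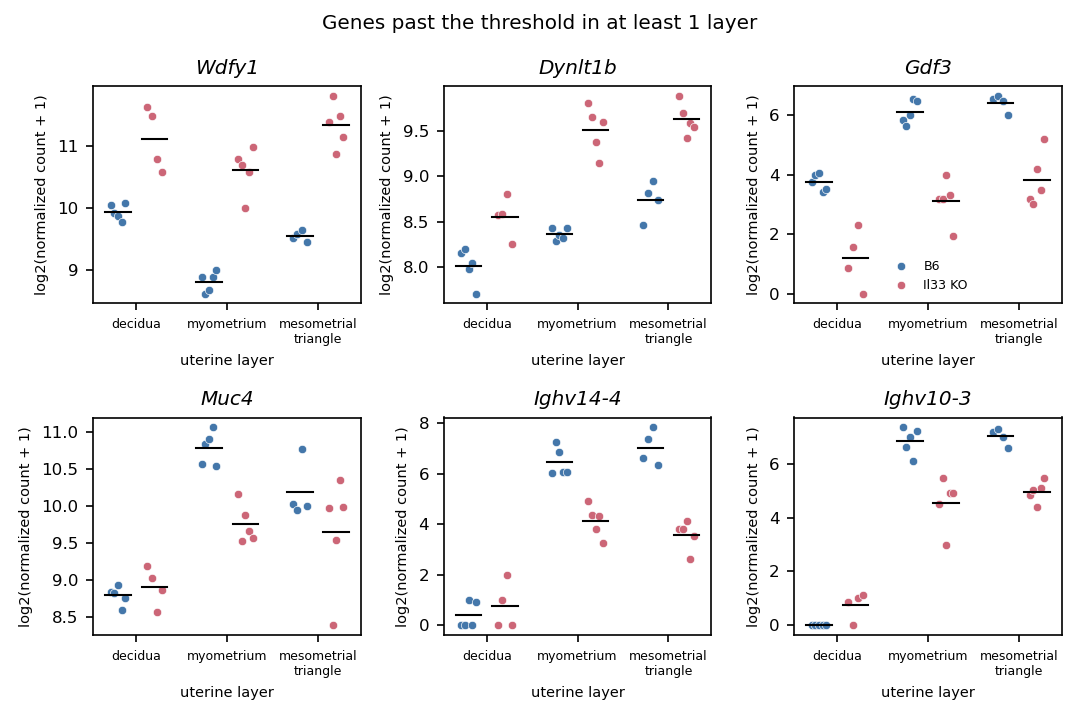
Normalized counts of 6 genes as log2 of the value + 1 by uterine layer, with 1 point per library and the group mean as a line, B6 in blue and Il33 KO in red. Wdfy1, Dynlt1b and Gdf3 kept 1 direction in the 3 layers, while Ighv14-4 and Ighv10-3 were near 0 in decidua.

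Lymphatic vessels drain the uterine wall and grow in pregnancy. All 6 genes of the lymphatic endothelium list were lower in Il33 KO myometrium (mean -0.44, camera adjusted p = 0.000128, adjusted p = 0.185 with an estimated correlation and 0.102 with fry). The hyaluronan receptor Lyve1 stood at -0.45, Mmrn1 at -0.46, Reln at -0.48 and the lymphatic master regulator Prox1 at -0.67, and these 4 fell when adjusted over the list alone, against 0 over all genes. Flt4, the VEGF-C receptor, stood at -0.33 and Pdpn at -0.26. The vascular endothelium list had a mean of -0.05 (camera adjusted p = 0.578).

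Genes of the IL-33 axis were lower in 5 of 5 (mean -1.30, camera adjusted p = 0.00103, adjusted p = 0.185 with an estimated correlation), and 2 fell when adjusted over the list alone against 1 over all genes: Il33 and its receptor Il1rl1, at -0.62. Without Il33 the list mean was -0.28 (camera adjusted p = 0.152). Genes known to differ between C57BL/6 substrains were higher in 2 of 3 (mean 0.69, camera adjusted p = 0.00103, adjusted p = 0.151 with an estimated correlation): Wdfy1 and the insulin-degrading enzyme gene Ide, at 0.48, rose when adjusted over the list alone, against 1 over all genes. With no filter on low counts the mean of this list was 0.13 and its call was lost (camera adjusted p = 0.138). Erythroid genes were higher in 7 of 7 (mean 0.88, camera adjusted p = 0.000341, adjusted p = 0.718 with an estimated correlation), with a mean of 0.56 without Il33 KO replicate 1. Cell cycle genes were lower in 10 of 11 (mean -0.25, camera adjusted p = 0.0170, adjusted p = 0.718 with an estimated correlation), with Mki67 at -0.44 and Top2a at -0.33; the call was lost without B6 replicate 5 (0.106) or Il33 KO replicate 4 (0.115). Interferon response genes were higher in 15 of 16 (mean 0.17, camera adjusted p = 0.0235, adjusted p = 0.743 with an estimated correlation). Without Il33 KO replicate 2 their mean was 0.02 (camera adjusted p = 0.731). The call was also lost without B6 replicate 2 or 4 (0.160 and 0.0821). With sample quality weights the interferon mean was 0.08 and the call was lost (camera adjusted p = 0.238). Fibroblast and matrix genes were lower in 12 of 13 (mean -0.20, camera adjusted p = 0.0235, adjusted p = 0.718 with an estimated correlation), with Col1a1 at -0.16 and Fn1 at -0.26. That call was lost without B6 replicate 2 or 4 (0.113 and 0.0516) or Il33 KO replicate 1, 2 or 5 (0.0553, 0.107 and 0.135). It was also lost with sample quality weights (mean -0.15, camera adjusted p = 0.197) and with the GC trend removed (mean -0.14, camera adjusted p = 0.107). For erythroid, cell cycle, interferon and fibroblast genes 0 passed over all genes and 0 when adjusted over the list alone.

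Mesothelium genes were higher in 4 of 6 (mean 0.27, camera adjusted p = 0.0300, adjusted p = 0.718 with an estimated correlation), and Upk3b at 0.58 and Lrrn4 at 0.48 rose when adjusted over the list alone, against 0 over all genes. Without B6 replicate 3 the mesothelium mean was 0.15 and the call was lost (camera adjusted p = 0.138), as it was without Il33 KO replicate 3 or 4 (0.0512 and 0.143) and with the GC trend of each library removed (0.0558) or the libraries above the median of Xist as a block (0.0676). B and plasma cell genes were lower in 5 of 7 (mean -0.48, camera adjusted p = 0.0300, adjusted p = 0.743 with an estimated correlation), with the plasma cell genes Igha at -0.65, Igkc at -0.52 and Jchain at -0.65. Cd79a at -1.02 and Mzb1 at -0.90 fell when adjusted over the list alone, against 0 over all genes. Jchain stood at 187, 258, 102, 52.8 and 47.2 CPM in Il33 KO myometrium replicates 1 to 5, against 134 to 211 CPM in B6. Without Il33 KO replicate 5 the B and plasma cell mean was -0.29 (camera adjusted p = 0.356), and the call was also lost without Il33 KO replicate 4 (0.143) or B6 replicate 2 or 5 (0.113 and 0.106). Single members fell when adjusted over the list alone in 2 lists with no call: Gzmc, a granzyme of uterine natural killer (NK) cells, at -1.12, and Alox15, a lipoxygenase of eosinophils, at -0.83. Of the 25 other lists tested in myometrium, the lowest camera adjusted p was 0.0888. The NK cell list had a mean of -0.09 against a median of 0.11 and an upward test.

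**Figure D3:**
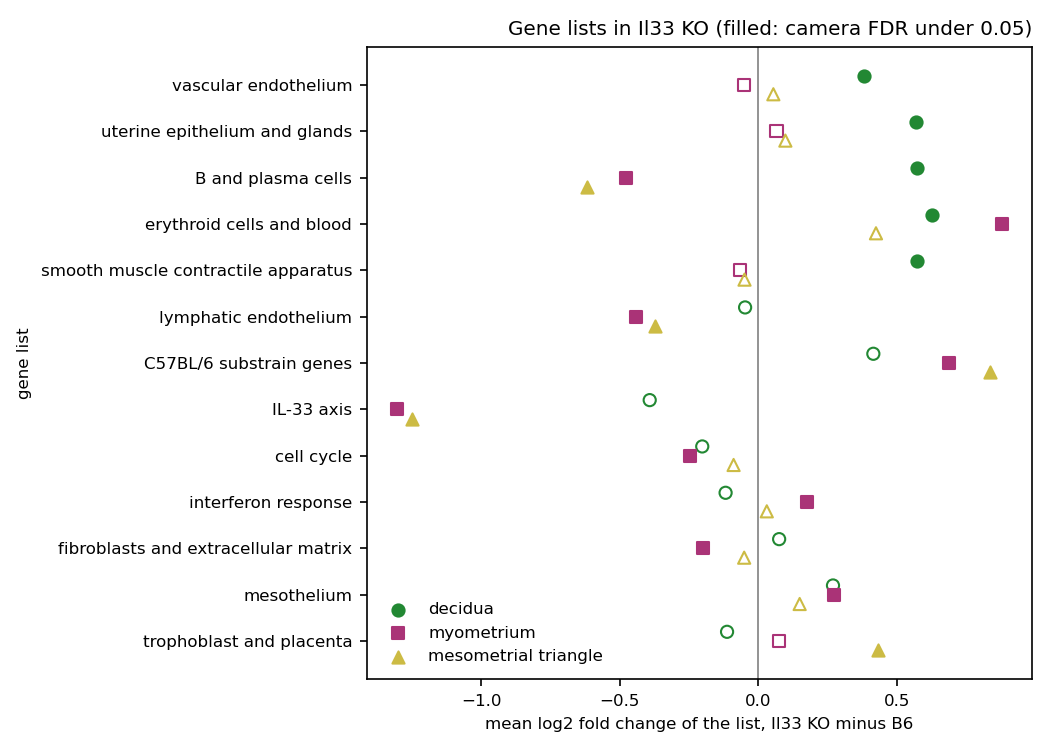
Mean log2 fold change (Il33 KO minus B6, horizontal axis) of each gene list with a camera adjusted p under 0.05 in at least 1 layer, with decidua as circles, myometrium as squares and mesometrial triangle as triangles, filled where the list passed. The lymphatic endothelium list stood at -0.44 in myometrium, -0.37 in mesometrial triangle and -0.05 in decidua.

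The mesometrial triangle comparison asked what IL-33 does where maternal vessels and uterine NK cells meet the implantation site. Wdfy1 rose, and Il33, Ighv14-4 and Ighv10-3 fell. NK cell genes did not pass, with Gzmd at 0.20 and the pore-forming gene Prf1 at 0.30 (list mean -0.05, median 0.15, camera adjusted p = 0.479 for an upward test). Dynlt1b and Gdf3 leaned as in myometrium without passing in the main limma fit, and each passed in 3 of 15 other settings.

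Of 16244 genes tested in mesometrial triangle, 5 passed limma, 2 higher and 3 lower, and 312 had an unadjusted p under 0.05 where chance gives 812. edgeR called 4, DESeq2 17, and the deposited statistics list 18. Wdfy1 went from 747 ± 42.3 to 2652 ± 644 normalized counts, a log2 fold change of 1.79 (SE 0.17, adjusted p = 0.0108). Il33 fell by 5.71 (SE 0.65, adjusted p = 0.0218). Ighv14-4 fell by 3.46, from 142 ± 67.9 to 11.7 ± 4.19 (adjusted p = 0.0218), and Ighv10-3 by 2.05, from 132 ± 27.7 to 31.5 ± 8.76 (adjusted p = 0.0383). Gm28438, under 1 CPM, had 4 reads in B6 and 248 in Il33 KO, a ratio of 49.2 (adjusted p = 0.0249). Some genes passed in DESeq2 and not in the main limma fit. Among them were Dynlt1b at 0.88 (adjusted p = 0.172), Gdf3 at -2.59 (adjusted p = 0.242) and Ighv9-2 at -2.80 (adjusted p = 0.422). So were the copper carrier gene Cp at -0.63 and AC102496.1 at 2.09 (adjusted p = 0.812 each), and Igkv6-25 at -2.36 (adjusted p = 0.968).

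The limma calls in mesometrial triangle depend on single libraries. The count was 0 without B6 replicate 1, 3 or 5 or Il33 KO replicate 1, 2 without B6 replicate 4 or Il33 KO replicate 3, and 3 without Il33 KO replicate 4. The highest adjusted p with 1 library left out was 0.0917 for Wdfy1, 0.133 for Il33, 0.141 for Ighv14-4, 0.316 for Ighv10-3 and 0.132 for Gm28438, each with its direction kept. Il33 KO mesometrial triangle replicate 5 stood apart, with a first principal component score of 115.6 and a correlation of its deviation with gene GC content of 0.524 across genes.

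The substrain genes were higher in 3 of 3 in mesometrial triangle (mean 0.83, camera adjusted p = 1.58e-07). This list alone among those called in the 3 layers stayed past the threshold with an estimated correlation (adjusted p = 0.020). Over 10 other settings its mean was 0.41 to 0.88. Wdfy1 led the list at 1.79, and no fit without Wdfy1 was run, so the call may restate 1 gene. Wdfy1 and Ide, at 0.43, rose when adjusted over the list alone, against 1 over all genes. Trophoblast genes were higher in 18 of 20 (mean 0.43, camera adjusted p = 7.54e-06, adjusted p = 0.517 with an estimated correlation), with Prl2a1 at 0.86 and Tpbpa at 0.46. Without B6 replicate 4 their mean was 0.08 (camera adjusted p = 0.114), and without Il33 KO replicates 3 and 4 in turn it was 0.17 and 0.65. All 6 lymphatic genes were lower (mean -0.37, camera adjusted p = 4.58e-05, adjusted p = 0.254 with an estimated correlation and 0.272 with fry), with Lyve1 at -0.52, Mmrn1 at -0.51, Reln at -0.35 and Prox1 at -0.60. B and plasma cell genes were lower in 5 of 7 (mean -0.62, camera adjusted p = 0.000432, adjusted p = 0.348 with an estimated correlation), with Igha at -0.98, Igkc at -0.83 and Jchain at -1.10. Jchain stood at 166, 352, 86.6, 68.2 and 37.1 CPM in Il33 KO replicates 1 to 5, against 192 to 272 CPM in B6. For trophoblast, lymphatic and B and plasma cell genes 0 passed over all genes and 0 when adjusted over the list alone. The IL-33 axis was lower in 5 of 5 (mean -1.25, camera adjusted p = 0.0119, adjusted p = 0.395 with an estimated correlation), and 1 gene, Il33, fell over all genes and when adjusted over the list alone. Without Il33 its mean was -0.13 (camera adjusted p = 0.534), and without Il33 KO replicate 5 the camera adjusted p was 0.0923. Of the 29 other lists tested, the lowest camera adjusted p was 0.0553.

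**Figure D4:**
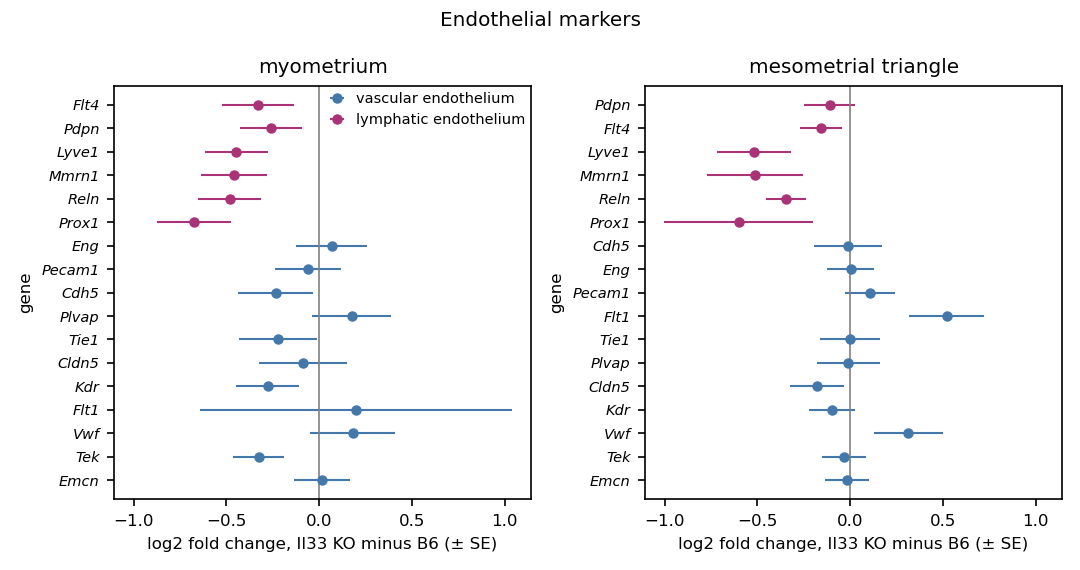
Log2 fold change (Il33 KO minus B6, horizontal axis) with SE as bars for lymphatic (purple) and vascular (blue) endothelial markers in myometrium and mesometrial triangle. The 6 lymphatic genes lay below 0 in both layers, from -0.26 (Pdpn) to -0.67 (Prox1) in myometrium and from -0.11 (Pdpn) to -0.60 (Prox1) in mesometrial triangle.

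In decidua the lymphatic endothelium list had a mean of -0.05, a median of 0.01 and an upward test (camera adjusted p = 0.864), and the substrain list a mean of 0.41 (camera adjusted p = 0.0962), with Wdfy1 past the threshold when adjusted over the list alone (adjusted p = 0.00181). The genes flanking Il33, listed because a knockout can carry linked donor sequence, had means of -0.11, -0.12 and -0.15 in decidua, myometrium and mesometrial triangle (camera adjusted p = 0.563, 0.493 and 0.328), and 0 of them were called by limma over all genes. 1 listed member, Kdm4c, lies on chromosome 4 in the files.

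Myometrium and mesometrial triangle shared 4 of their called genes. Wdfy1 and Gm28438 rose in both, where independent lists share 0.000392 higher genes. Il33 and Ighv14-4 fell in both, where independent lists share 0.00117 lower genes. Il33 is the deleted gene, and both layers compare the same genotypes. The lists are thus not independent, and these expectations are no test of the overlap. Gm28438 was called in the 3 layers. Gdf3, Ifi208 and Dynlt1b were not called in decidua in the main fit but leaned as in myometrium. In the fit of all 28 libraries they stood there at -2.59, -2.70 and 0.62, and B6 and Il33 KO libraries did not overlap. Ifi208 had 49 reads in the 5 B6 decidua libraries and 3 in the 4 of Il33 KO.

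The interaction asks whether the genotype effect differs between layers. In each contrast with decidua 1 antibody segment passed. Ighv10-3 was called for decidua minus myometrium, a difference of 3.11 (SE 0.52, adjusted p = 0.0448), and Ighv14-4 for decidua minus mesometrial triangle, a difference of 3.84 (SE 0.64, adjusted p = 0.0452). Both were nearly unread in decidua, with 0 reads in B6 and 3 in Il33 KO for Ighv10-3 and 2 and 4 for Ighv14-4. No genotype effect could be measured there, so these differences are no evidence of a different effect in decidua. Neither passed in the other contrast: Ighv14-4 had an adjusted p of 0.451 for decidua minus myometrium and Ighv10-3 0.0769 for decidua minus mesometrial triangle. The Il33 effect differed by 4.21 between decidua and myometrium (adjusted p = 0.193) and by 4.41 between decidua and mesometrial triangle (adjusted p = 0.114), neither past the threshold. Between mesometrial triangle and myometrium limma called 0 genes, with 190 at an unadjusted p under 0.05, edgeR 0 and voom 0. Each of the other contrasts gave 1 gene in limma and 0 in edgeR and voom. With each of the 28 libraries left out in turn, the count was 0 in 18 of the fits for decidua minus myometrium and in 17 for decidua minus mesometrial triangle.

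The B6 layers were compared to show what each dissected layer holds. B6 decidua carried placental transcripts at high levels. Prl3b1 stood at 14308 ± 1723 CPM in decidua and 104.5 ± 202 CPM in myometrium (log2 fold change 9.99), and Tpbpa at 17767 ± 2461 against 112 ± 214 CPM (9.72). All 21 trophoblast genes tested were higher in decidua than in myometrium, as were the pregnancy-specific glycoprotein pseudogene Psg-ps1 (10.17), the prolactin family genes Prl3a1 (10.12) and Prl8a2 (6.01), and Flt1 (6.51), the VEGF receptor gene of trophoblast and endothelium. Gata3 (6.26), a trophoblast and lymphoid regulator, Kit (4.97) and Ptgs2 (6.29) were higher too, and all 4 Y-linked genes, which mark male fetal cells. The myometrium-type genes were far lower in decidua: Actg2 (-9.02), Cnn1 (-8.70), Myh11 (-8.66) and Acta2 (-8.05) of the contractile apparatus, and the matrix genes Eln (-8.31), Col6a2 (-8.21) and Col1a1 (-6.65). All 13 smooth muscle genes and all 11 cell cycle genes were lower.

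Plasma cell, macrophage, antigen presentation and mast cell genes were lower in B6 decidua than in myometrium. The plasma cell genes Igha (-7.18) and Igkc (-7.54), the antigen presentation gene Cd74 (-4.69), the macrophage mannose receptor Mrc1 (-5.36), and the mast cell tryptase Tpsb2 (-7.12) fell. All 7 B and plasma cell genes, 9 of 10 MHC class II genes, 10 of 12 alternatively activated macrophage genes and 8 of 9 mast cell genes were lower. T cell genes were lower in 8 of 10, and of eosinophil genes 4 of 7 fell and 2 rose. The decidua libraries also held placental transcripts, so lower shares of reads need not mean fewer such cells in the maternal tissue. Some immune lists leaned higher or were mixed: 11 of 16 interferon response genes rose and 3 fell, 6 of 10 genes of group 2 innate lymphoid cells rose and 3 fell, and 5 of 10 NK cell genes rose and 4 fell. In limma 12886 of 16988 genes differed between decidua and myometrium, 6535 higher and 6351 lower, and 7704 of them by a log2 fold change of at least 1. Of these named genes the highest adjusted p was 5.6e-05, for Prl3a1. B6 myometrium replicate 5 held 493 CPM of Tpbpa against 3.66 to 48.6 CPM in the other B6 myometrium libraries, and without it the log2 fold change was 10.86 for Tpbpa and 11.25 for Prl3b1.

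The mesometrial triangle differed from myometrium first in granzymes. Gzmf (8.70), Gzmg (8.31), Gzmd (8.16), Gzme (7.73) and Gzmc (6.40), and the pore-forming gene Prf1 (6.17), were higher, as were 7 of 10 NK cell genes. Gzmd stood at 523 ± 108 CPM in mesometrial triangle and 2.47 ± 2.47 CPM in myometrium. All 16 interferon response genes were higher, with Irf7 at 2.06 and Oasl2 at 1.23. The matrix proteases Mmp11 (3.81) and Mmp14 (1.64), the endothelial cadherin Cdh5 (2.21) and the trophoblast genes Prl2a1 (5.28) and Prl7b1 (6.28) were higher. Of their lists, 8 of 16 matrix protease genes rose and 1 fell. Vascular endothelium had 4 of 11 genes higher and 0 lower, and trophoblast 5 of 21 higher and 0 lower. Myometrium held more of the gland genes Prss28 (-3.53), Stra6 (-2.89), Ltf (-1.43) and Krt7 (-1.20), of Col1a1 (-1.50) and of the mast cell proteases Cma1 (-1.59), Mcpt4 (-1.53) and Tpsb2 (-1.49). 10 of 13 uterine epithelium genes, 9 of 11 cell cycle genes and 6 of 9 mast cell genes were lower in mesometrial triangle.

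In limma 4252 of 16988 genes differed between mesometrial triangle and myometrium, 2237 higher and 2015 lower, and 1452 of them by a log2 fold change of at least 1. Scaling by library size alone moved the median of all genes by 0.19 and gave 3906 higher and 1042 lower. Of the genes named for this contrast other than Tpbpa, the highest adjusted p was 0.0122, for Tpsb2. Tpbpa was higher by 4.04 (adjusted p = 0.0282), a call lost in edgeR (adjusted p = 0.317). It was also lost without B6 myometrium replicate 1, 2 or 3 (0.0586, 0.0628 and 0.0532) or B6 mesometrial triangle replicate 1, 3 or 5 (0.0616, 0.0751 and 0.0703). Without B6 myometrium replicate 5, the library with 493 CPM, the change was 5.18 (adjusted p = 0.000202).

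Against mesometrial triangle, B6 decidua was again higher in placental genes, with Prl3a1 at 9.89, the cathepsin Cts3 at 9.81 and Prl3b1 at 9.74, and 20 of 21 trophoblast genes were higher. It was lower in the complement gene C7 (-7.84), the acute phase gene Crp (-7.97), the oxytocin receptor Oxtr (-6.43), Igha (-7.19), Cd74 (-4.51) and Mrc1 (-4.85). The NK cell genes Gzmd (-2.09) and Prf1 (-2.72) were lower, as were 9 of 10 of that list. Ptgs2 stood higher in decidua by 2.80. In limma 11333 of 16988 genes differed, 5572 higher and 5761 lower, and 6536 of them by a log2 fold change of at least 1. Scaling by library size alone moved the median of all genes by -0.20 and gave 4081 higher and 7100 lower. Of the genes named here the highest adjusted p was 0.0185, for Gzmd.

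**Figure D5:**
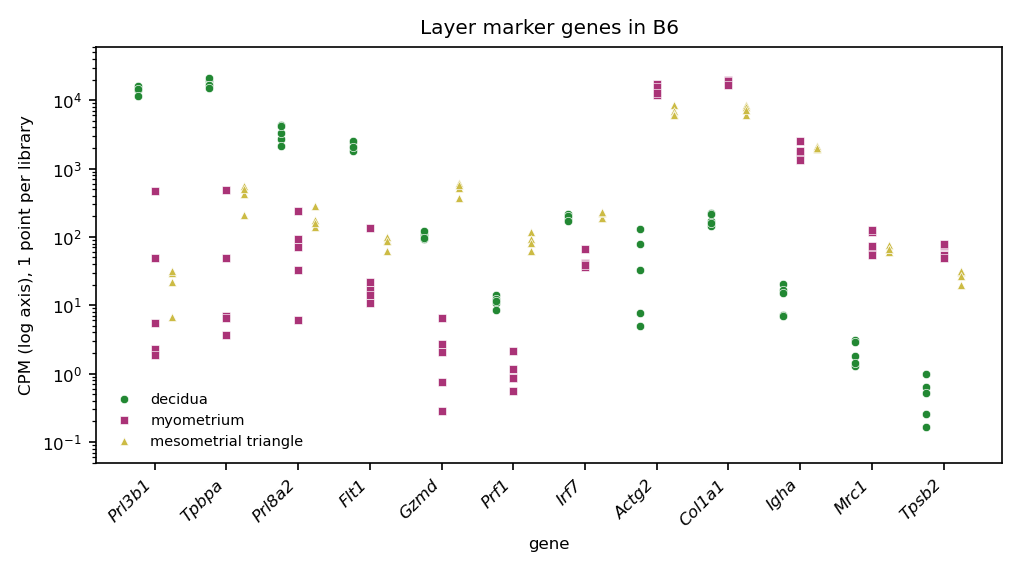
CPM of the recovered reads (log axis) for 12 marker genes in the B6 layers, with 1 point per library, decidua as circles, myometrium as squares and mesometrial triangle as triangles. Prl3b1 and Tpbpa lay highest in decidua (14308 and 17767 CPM on average), Gzmd in mesometrial triangle (523 CPM), and Actg2 and Col1a1 in myometrium (14029 and 18283 CPM).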

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

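The tests of the genes called beside Il33 were chosen after those calls were seen, and the splits that take the list of smallest p after the other splits of the lymphatic list were seen. The Xist block was chosen after seeing the data. The tests of the other patterns were written beforehand.

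The differences between layers rested on 1 antibody segment each. The genotype effect on Ighv10-3 differed by 3.11 (log2) between decidua and myometrium, and that on Ighv14-4 by 3.84 between decidua and mesometrial triangle, each by the interaction test. Ighv10-3 had 3 reads in the decidua libraries together and Ighv14-4 had 2 in B6 and 4 in Il33 KO, so no genotype effect could be measured in decidua and these differences are no evidence of a different effect there. Single libraries far from the others of their group were B6 decidua replicate 2 for Gm28438 (0.9 normalized counts, the others at 0), B6 mesometrial triangle replicate 4 for Muc4 (1744 normalized counts), B6 mesometrial triangle replicate 1 for the share of reads in its top 10 genes (13.4%), and B6 decidua replicate 5 and B6 mesometrial triangle replicate 5 for the first principal component (-34.2 and -25.2). These are 5 of 84 groups tested, and 4.2 are picked out by chance at 1 in 20.

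In 2 layers 1 Il33 KO library stood apart from the rest of its group. Il33 KO decidua replicate 4 and Il33 KO mesometrial triangle replicate 5 set the first principal component of their layers, which held 71.3% and 51.5% of the variance. Without the decidua library the mean log2 fold change fell from 0.57 to 0.17 for gland markers and from 0.63 to 0.13 for blood markers, and muscle markers kept 0.42 of 0.57; the 3 calls ended. A layer mislabelled as another is argued against for the decidua library, which correlated better with its own layer by 0.120. For the mesometrial triangle library the margin was 0.0137, which cannot decide this. B6 myometrium replicate 5 correlated at 0.964 with its own layer and at 0.960 with another. The mesometrial triangle library held 15910 CPM of Acta2, against 7337 to 10523 CPM in the others of its layer. The cause was not tested. A bias with gene GC content is a candidate explanation, with Spearman correlations across genes of 0.740 and 0.524. Other libraries of these groups came close in size with the opposite sign: -0.695 and -0.643 in Il33 KO decidua replicates 1 and 2, and -0.456 in Il33 KO mesometrial triangle replicate 2. The nuclear RNA Malat1 was 22.2 and 62.9 CPM in the libraries that stood apart, against 404 to 1992 and 285 to 2373 CPM in the others of their layers. With transcript length they were -0.347, exceeded in size by the 0.381 of Il33 KO decidua replicate 1, and -0.256. A bias with length stays open, and no biological explanation was tested.

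Beside Il33, 9 genes were called in at least 1 layer: Wdfy1, Dynlt1b, Gdf3, Muc4, Ighv14-4, Ighv1-80, Ighv10-3, Ifi208 and Gm28438. Sequence linked to Il33 and carried from a donor strain is argued against as their source, since 0 of the 9 lie on chromosome 19. The labels give no substrain for either genotype. A difference in strain background elsewhere in the genome, if there is one, cannot be told apart from the knockout, since it would follow the genotype. Of the 9 genes, 5 kept 1 direction in the 3 layers, which either would give. Ighv14-4, Ighv1-80 and Ighv10-3 had at most 9 reads per genotype in decidua, so their direction there could not be measured. Muc4 stood at 0.20 (SE 0.26) in decidua in the fit of all 28 libraries. Wdfy1 stood on the list of C57BL/6 substrain genes. For Gm28438, a copy of mitochondrial mt-Nd3 with 99.71% identity, reads of another mitochondrial sequence could be the source: mt-Nd3 stayed at or under 0.602 CPM, with no read in the 14 Il33 KO libraries and in 3 of the 14 B6 libraries.

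Lymphatic endothelial genes, Lyve1, Prox1, Reln, Mmrn1, Flt4 and Pdpn, were lower in Il33 KO myometrium and mesometrial triangle. These layers may come from the same mice, so they need not be independent observations. The list calls were lost with an estimated correlation (adjusted p = 0.185 and 0.254) and with fry (0.102 and 0.272). Fewer vessels of every kind in the dissected tissue would lower both lists. The vascular mean lay above the lymphatic mean by 0.390 (SE 0.0823) in myometrium and 0.428 (SE 0.103) in mesometrial triangle. These SE are over the genes of the lists and leave out the spread between mice. They cannot decide the question over mice, but in these libraries the vascular list did not fall as the lymphatic list did. Gene length, GC content and expression level are argued against by 10000 matched random lists. Their median was -0.06 in myometrium and -0.02 in mesometrial triangle. A mean as low came in 0.01% of them in each layer, the smallest share they can give. Random genes need not share the correlation of list members, so this share does not measure chance. With sample quality weights the means were -0.39 and -0.34. Chance in the grouping of the libraries was not excluded. In myometrium 2 of 100 splits, the real one included here and below, gave a mean as far from 0 (0.44 against at most 0.47 in another split), but this list was singled out there as that of smallest camera p. With the list of smallest p taken in each split, 65 of 100 splits had a p as small (-log10 p of 5.42 against at most 46.5). In mesometrial triangle 7 of 100 splits gave a mean as far from 0 (0.37 against 0.49). A lower lymphatic content in Il33 KO was not tested directly and stays open, as does the strain background. Counts of lymphatic vessels in sections, with controls of matched background, would test these.

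Splits of the same libraries, 100 per comparison, argued against chance for the count of genes called within layers. They test no single gene, and the counts in myometrium and mesometrial triangle include Il33, the deleted gene. As many genes were called in 1 split in decidua (1 gene, at most 0 in another split), 4 in myometrium (9 genes, at most 1255) and 1 in mesometrial triangle (5 genes, at most 1). The split of myometrium with 1255 genes set B6 replicates 1, 3 and 5 and Il33 KO replicates 2 and 5 against the rest, which points to a structure among these samples other than genotype. These 5 libraries held 82.9 to 122 CPM of Xist and 311 to 492 CPM of Neat1, both nuclear RNAs, and the others 27.6 to 56.4 and 148 to 304 CPM. With the libraries above the median of Xist as a block, 10 genes and 11 lists were called between the genotypes. Chance was not excluded for the gene lists, with 33 splits in decidua (5 lists, at most 9), 11 in myometrium (9 lists, at most 12) and 36 in mesometrial triangle (5 lists, at most 11). It was not excluded for the interactions either, with 9 splits for decidua minus myometrium (1 gene, at most 67) and 9 for decidua minus mesometrial triangle (1 gene, at most 1245). For mesometrial triangle minus myometrium the real count was 0, which all 100 splits reach, so nothing was tested (at most 88 in another split). Such counts also point to structure among samples. For the B6 layers only the real split gave as many genes, 1 split each. Any other split mixes layers within a group, which widens the spread there. Fewer calls were therefore nearly fixed in advance, and these splits do not test chance. The counts were 12886 genes against at most 7 for decidua and myometrium. They were 4252 against 3226 for mesometrial triangle and myometrium, and 11333 against 8935 for decidua and mesometrial triangle.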

How the results depend on the processing

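TMM scaling, library size scaling for the interactions and the B6 layers, edgeR, the pseudocounts of 0.5 and 5, sample quality weights, removal of the GC trend, the Xist block, the list without Il33 and the joint omission of both libraries that stood apart were chosen after seeing the data.

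Named genes, called or not, kept their direction in the genotype comparisons. Of 309 pairs of a gene and a library left out, 266 stayed on their side of the threshold. Of 507 pairs of a gene and another setting, 451 did. Genes not called count as staying when they remain uncalled. With a library left out, called genes kept their call in 9 of 9 fits in decidua and 7 to 10 of 10 in myometrium. In mesometrial triangle Wdfy1 kept it in 5 of 9, Il33 in 4, Ighv14-4 in 3, and Ighv10-3 and Gm28438 in 1 each. The pairs that stayed on their side were 144 of 180 and 145 of 200 for the lists. They were 1219 of 1232 and 699 of 704 for genes of the B6 layers, and 125 of 168 and 44 of 60 for interactions. The uterine epithelium list in decidua was the exception in direction, with a mean of 0.29 under sample quality weights and 0.17 to 0.82 with a library left out, where its test turned down without Il33 KO replicate 4. The cause was not tested.

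The count of genes called in decidua, 1, was 3 with DESeq2, 4 in the fit of all 28 libraries, 3617 with sample quality weights and 3 with the GC trend removed; leave-one-out gave 1 to 1. The weights give Il33 KO decidua replicate 4 a weight of 0.0306, yet the fit without it called 1 gene. In myometrium 9 became 29 with DESeq2 and 6 to 17 with a library left out. In mesometrial triangle 5 became 17 with DESeq2, 8 in the fit of all 28 libraries, 1 with trophoblast genes as a covariate, 2 with a pseudocount of 0.5, 23 with sample quality weights, and 0 to 7 with a library left out. The cause was not tested.

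The lists called in decidua, 5, were 0 with an estimated correlation, 0 with fry, 9 with the GC trend removed and 2 to 6 with a library left out. Sample quality weights gave 7 lists, none of them among these 5 (adjusted p = 0.243 to 0.736). In myometrium 9 became 0, 2 with fry and 6 to 12, and in mesometrial triangle 5 became 1, 1 with fry and 4 to 9. The test with an estimated correlation takes its degrees of freedom from the libraries in place of the genes, which widens it by construction; what the correlation itself adds was not separated.

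For the interactions, the 1 gene of decidua minus myometrium became 0 with voom, library size scaling, edgeR, the GC trend removed or both apart libraries omitted, and 3 with a pseudocount of 5. The 1 gene of decidua minus mesometrial triangle became 2 with no filter, 0 with voom, edgeR, a pseudocount of 0.5 or the GC trend removed, and 3 with a pseudocount of 5. A library left out gave 0 to 3 for each, and 0 to 0 for mesometrial triangle minus myometrium, where the settings run gave 0. The cause was not tested.

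A log2 fold change of at least 1 left 7704, 1452 and 6536 genes between the B6 layers, by construction. With a library left out the counts were 12446 to 13034 for decidua and myometrium, 3072 to 4783 for mesometrial triangle and myometrium, and 10816 to 11545 for decidua and mesometrial triangle.

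Whether replicate numbers pair the samples stayed open, since pairs of different numbers were not compared. Jchain had the same order over Il33 KO replicates 1 to 5 in myometrium and mesometrial triangle. Over all genes, same-numbered Il33 KO libraries of these layers correlated at 0.40, 0.40, 0.44, -0.21 and -0.31. Layers may thus share mice, and the main fits of all 28 libraries and of the B6 layers took libraries as independent. Between genotypes 4 of 13 same-numbered pairs correlated over 0.1 (-0.64 to 0.27), and between layers of a genotype 12 of 26 (-0.31 to 0.63). With the number as a block, calls within layers were 1 gene and 7 lists in decidua, 9 and 10 in myometrium, and 0 and 6 in mesometrial triangle. In myometrium Ighv1-80 (adjusted p = 0.0722) and Muc4 (0.0659) lost their calls with the block. The block gave 0 genes for each interaction and 12961, 3887 and 11403 between the B6 layers. Depth limits Il33 in decidua, at 19 reads in B6. The planned size factor alternative was not run, as the deposited values carry it already.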

Other observations

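Ptgs2, the gene of the inducible prostaglandin synthase, stood outside the calls reported for decidua. Of 24 other settings it passed in 2, both chosen after seeing the data. With the GC trend of each library removed it fell by 1.23 (SE 0.14, limma adjusted p = 0.0286) in Il33 KO decidua, and with sample quality weights, a fit that called 3617 genes, by 0.73 (adjusted p = 0.0214). Without these steps it stood at -1.61 (adjusted p = 0.935), and in the other settings the lowest adjusted p was 0.455. Without Il33 KO replicate 4 it stood at -0.96 (adjusted p = 0.506). In the fit with the GC trend removed Wdfy1 passed in decidua at 1.34 (adjusted p = 0.0286), Lhfpl2 passed in myometrium at -0.63 (adjusted p = 0.0408), and Ifi208 passed in mesometrial triangle at -3.69 (adjusted p = 0.0435), while Ighv10-3 no longer did there (adjusted p = 0.0931).

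Nnt, a nuclear gene of a mitochondrial enzyme on the list of C57BL/6 substrain genes, stayed at or under 0.327 CPM in every library of both genotypes. Of the 13 mitochondrial protein-coding genes, 5 were at 0 in every library, so the mitochondrial list rests on the others. Placental Tpbpa reached 493 CPM in B6 myometrium replicate 5, and 440 and 195 CPM in Il33 KO myometrium replicates 2 and 3, against 1.15 to 48.6 CPM in the other myometrium libraries. Plasma cell Jchain was 102 CPM or lower in Il33 KO myometrium replicates 3, 4 and 5 and 134 CPM or higher in the other myometrium libraries.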
